A study of Mus musculus with 6 samples.

How the data were processed

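Total RNA from mouse embryonic fibroblasts was measured on 6 single-colour (Cy3) Agilent arrays, 1 for each combination of 3 genotypes (wild type, Clk/Clk and Per2m/m) and a mock or an H-Ras and SV40T expressing vector. Samples were grouped by their titles, which carry both the genotype and the transfection, and each group held 1 array. The arrays lay on 1 slide and were scanned together, so slide and scan were not batches to test. Position on the slide followed genotype in part, since the wild type and Clk/Clk arrays lay in slide row 1 and both Per2m/m arrays in slide row 2. With 1 array per group no spread between repeats of a group was measured, and the p-values of single genes below measure only the spread between these 6 samples. The p-values of gene lists at a preset correlation compare the genes of a list with all other genes. They rest on the spread between genes under that assumed correlation, not on the spread between samples.

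The deposited scanner output gives a fluorescence intensity per spot, on a linear scale. Per the file headers, it was extracted with Feature Extraction 10.7.1.1, with spatial detrending, multiplicative detrending and surrogate values for spots near background switched on. The submitters' processing notes name Feature Extraction 9.5.1.1, and the difference between both versions was left open. The authors' deposited table of the whole series also holds intensity on a linear scale. Its 6 columns each had a median of 23.8 and held the same sorted values, and they followed the log2 processed signal of their own array with r of at least 0.998 across probes, so it was used as quantile-normalized processed signal, not centred by gene. The software behind that table is not given in the sources used here.

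Each array carried 59305 spots that were not controls. Between 85 and 125 spots per array were left out as outliers, 49.3% to 57.3% were well above background, and 0 were saturated. The transfected Per2m/m array had the lowest share well above background, against 53.5% to 57.3% on the other arrays. Its median signal was 18.5, against 26.1 to 28.95 on the others, while its 75th percentile of 420 lay inside their range of 377 to 634. Repeated spots of a probe had a median SD of 0.05 to 0.06 (log2) on every array, which gives a spread of 0.08 for a ratio of 2 arrays and 0.11 for a difference of 2 ratios. These values cover spot noise only. The number of arrays limits the precision of every comparison.

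Spots of a probe were averaged. The values analysed were log2 of the processed signal minus the array's 75th percentile of it, called levels below. Of 55681 probes, 27235 were named through a RefSeq accession, 3581 through a symbol and 565 through a synonym, in a gene table of assembly GRCm38.p6 that was used for names only. A further 1145 kept the name in the file, and 23155 stayed unnamed and were not analysed here. Probe coordinates are those of the files, on build mm9 (NCBI37). A probe was kept when it was well above background on at least 1 of the 6 arrays, and each gene was represented by its kept probe with the highest mean level, which left 17282 of 23410 named genes, 12653 of them well above background on all 6 arrays. A gene well above background on no array of a group has only a bound there. Its change is given as at least N-fold, from the mean level of the brighter group against the dimmer group's mean of, per array, the higher of the probe's own level and the lowest level among probes well above background.

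An additive model of genotype and transfection was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05). It leaves 2 residual degrees of freedom, which hold array noise and genotype-specific response together. Its coefficients were transfected minus mock, Per2m/m minus wild type and Clk/Clk minus wild type, and values after ± are their standard errors. Within each genotype the log2 ratio of the transfected to the mock array is called the response. It has no test, and genes were counted at a size of at least 2-fold with the brighter array well above background. Where a gene was well above background on only some arrays of a group, its coefficient used the measured values of all arrays, so its size and rank rest in part on values below the bound. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for reading files and drawing.

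Before the data were examined, the comparisons, the alternatives, the rule for named genes and 33 gene lists were fixed. The lists covered the core clock, CLOCK-BMAL1 E-box targets, aldehyde dehydrogenases, drug efflux transporters, NRF2 targets, aryl hydrocarbon receptor targets, glutathione transferases and UGTs, folate and thymidylate, DNA replication and E2F, mitosis, p53 targets, senescence regulators, RAS-MAPK output, RAS genes, secreted inflammatory factors, interferon-stimulated genes, collagen and matrix, the contractile actin cytoskeleton, glycolysis, cholesterol synthesis, the BCL2 family, DNA repair, heat shock and immediate-early stress, HOX genes, sex-linked genes, and markers of macrophages, endothelium, epithelium, skeletal muscle, neural cells, adipocytes, cartilage and fibroblasts. The 32 lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01 between genes, adjusted over lists and coefficients, and again with camera at an estimated correlation and with fry. List medians of single-array ratios were placed among those of 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these arrays.

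The rule for named genes took Aldh3a1, Per2, Clock and Hras, and members of the core clock and aldehyde dehydrogenase lists that matter to a comparison. It also took, for each coefficient, the 10 highest and 10 lowest log2 fold changes among genes with an adjusted p under 0.05, the same direction in every genotype or both transfection states, and a signal well above background on every array of the higher side. Where fewer than 10 passed, the places were filled by size from genes that met the other conditions. For each difference in response, the 10 highest and 10 lowest genes well above background on all 4 arrays were taken, and, for each gene list, up to 4 members with the largest size of change. Uncharacterised loci were counted but not named, and some genes that the rule took are not reported here. Other genes named in the text were chosen after their values were seen.

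Alternatives were normexp background correction (offset 50), quantile normalization, scaling to each array's median, the authors' table, probes well above background on all 6 arrays, no filter on dim probes, a floor at the lowest signal well above background, the mean over a gene's probes, an intensity trend in eBayes, fits without the genotype block or the transfection term or with only the arrays of the genotypes compared, a 4-fold threshold, and leaving out each array or each pair. The additive gene model was tested on simulated data with known answers, on 17282 genes, and the alternative models were not. With the spread of the real data, 0% of the genes changed by a log2 of 1, 2 or 4 passed the adjusted threshold in each of the 3 comparisons, with median transfection estimates of 1.01, 2.02 and 4.01 and 0 false calls. With an SD of 0.1 (log2), 100% passed at each size, with 10, 9 and 13 false calls for transfection, Per2m/m and Clk/Clk. With the real spread, camera called the 1 of 30 lists of 30 genes that had been moved by a log2 of 1, at adjusted p of 1.55e-14, 1.82e-11 and 5.6e-10 in the same order, and 0 others. The simulated genes varied independently of each other. In the real data the estimated correlation within the called lists ran from −0.01 (p53 targets) to 0.87 (mitosis). The simulation therefore cannot tell how often camera calls a list of correlated genes falsely.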

Results

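Gene expression was measured in cultures of mouse embryonic fibroblasts (MEFs), connective tissue cells grown from embryos, of 3 genotypes: wild type, Clk/Clk, which the series design describes as mutant in Clock, and Per2m/m. By the labels, cells of each genotype had received a mock or a vector expressing H-Ras and SV40T. The source name of the transfected Per2m/m sample is worded differently and does not name SV40, so it is open whether these cells received the same vector, which bears on every Per2m/m response below. H-Ras is a small GTPase that becomes an oncogene when activated, and the SV40 T antigen is a viral protein that binds p53 and RB. Each of the 6 groups was measured on 1 array, so no group had replicates. Levels are log2 signals over the array's 75th percentile. The title of the series points to Aldh3a1 in oncogenic cells with a faulty Per2, and the design allows transfected to be compared with mock cells in each genotype and the genotypes with each other.

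The altered genes were read on every array. Per2, which encodes a repressor of the circadian clock, was read by a probe at chromosome 1, 93313046 to 93313105 (mm9), position 5290 of its transcript. Its level was −3.37 in mock and −2.38 in transfected wild type cells, −3.91 and −3.88 in Clk/Clk cells, and −0.98 and −2.82 in Per2m/m cells. Clock, which encodes an activator of the same clock, was read at chromosome 5, 76641377 to 76641436, with levels of 0.49 and 0.70 in wild type, −0.30 and −0.05 in Clk/Clk and 0.34 and 0.78 in Per2m/m cells. The difference of Clock between Clk/Clk and wild type was −0.77 ± 0.30 (limma, adjusted p = 0.556), and that of Per2 between Per2m/m and wild type 0.97 ± 0.79 (adjusted p = 0.936). The labels do not say which part of either gene is altered, so neither probe is known to lie inside it and these values check no label. Hras, at chromosome 7, 148377296 to 148377355, had responses of −0.17 in wild type, 0.64 in Clk/Clk and −1.33 in Per2m/m cells, and a dimmer probe gave 0.15 in wild type, at least 0.78 in Clk/Clk, where it was not well above background on the mock array, and −0.15 in Per2m/m cells. The species of the H-Ras in the vector is not given in the sources used here, and SV40T was not analysed here, so the transfection itself was not read.

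The transfected Per2m/m array stood apart from the other 5. Its correlation with them across genes lay between 0.854 and 0.892, while the median correlation of each other array with the rest was 0.931 to 0.945, and the Clk/Clk pair reached 0.981. The transfected Per2m/m array also had the smallest share of spots well above background, at 49.3%. Xist, the RNA that silences an X chromosome, and the Y-linked genes Ddx3y and Eif2s3y were all well above background on the mock Per2m/m array, at −0.53, −0.05 and −0.81. On the transfected Per2m/m array all 3 were not well above background, a difference of at least 16.7-fold, 23.2-fold and 13.7-fold. Both wild type arrays carried Xist, Ddx3y, Eif2s3y and Uty, and both Clk/Clk arrays carried the Y-linked genes with Xist not well above background. The 4 measured sex-linked genes were too few for a list test, with median responses of −0.11 (−0.18 to 0.20 over scalings), −0.22 (−0.36 to −0.22) and −5.85 (−5.85 to −2.33) in wild type, Clk/Clk and Per2m/m cells.

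**Figure D1:**
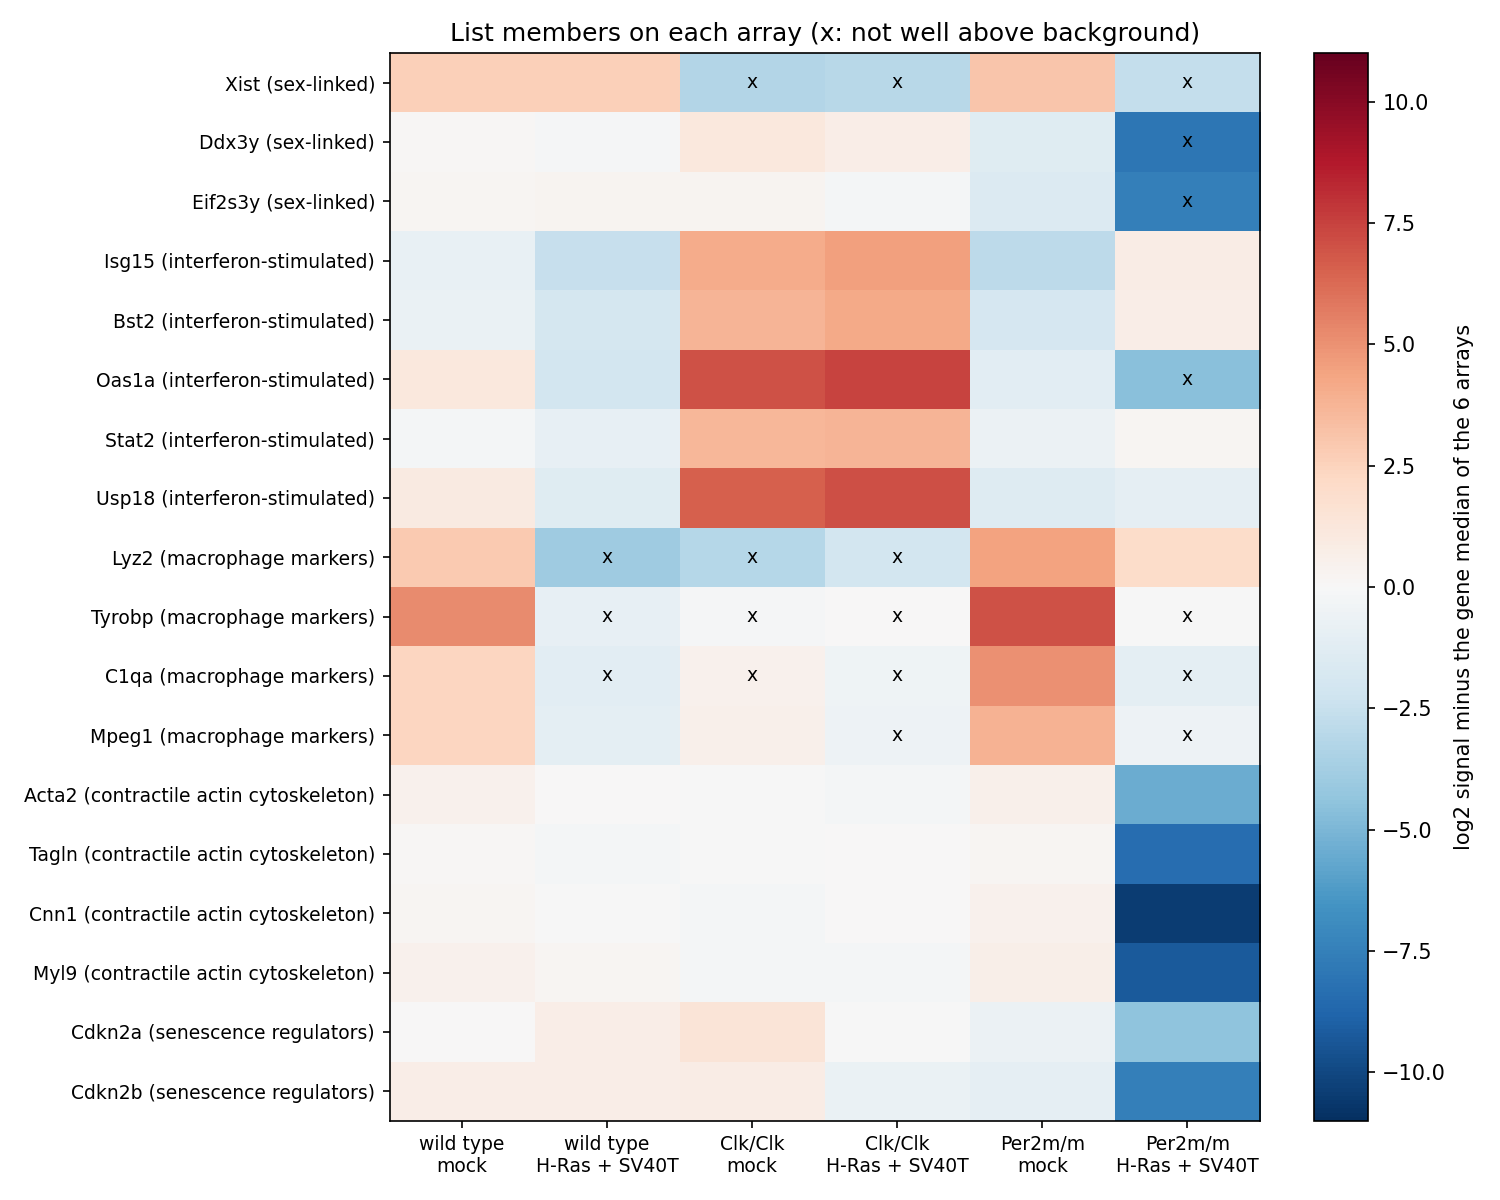
Members of 5 gene lists on the 6 arrays (columns), coloured by log2 signal minus the median of that gene over the 6 arrays, with x where the gene was not well above background. The interferon-stimulated genes shown were higher on both Clk/Clk arrays, the 4 contractile and 2 senescence genes shown lower on the transfected Per2m/m array, where the 3 sex-linked genes were not well above background.

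The comparison of transfected with mock cells over all 3 genotypes asks what the vector was accompanied by regardless of genotype. Genes of DNA replication were higher, with 33 of 35 positive and a median of 0.95. Mcm2, a subunit of the replicative helicase, was higher by 1.54 ± 0.32 and in every genotype, with responses of 1.35 in wild type, 1.16 in Clk/Clk and 2.10 in Per2m/m cells. Dscc1, which helps to load the sliding clamp, was higher by 1.90, Cdt1, a licensing factor, by 1.39, and Pola1, a DNA polymerase subunit, by 1.37. Mitosis genes were positive in 24 of 25 with a median of 0.79, with the checkpoint kinases Ttk and Bub1b at 1.20 and 1.07, and DNA repair genes in 28 of 34 with a median of 0.63, with the recombination gene Rad54l at 1.12. Cholesterol synthesis genes were positive in 20 of 21 with a median of 0.56, although their median response in Clk/Clk cells was −0.35. Sqle, an enzyme early in sterol formation, had responses of 1.22, −0.10 and 3.70 in wild type, Clk/Clk and Per2m/m cells.

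Genes of collagen and matrix were lower after transfection, with 28 of 30 negative and a median of −1.13. Thbs1, a matrix protein that binds cells and growth factors, stood at −3.93, Col12a1, a fibril-associated collagen, at −3.52 and Dcn, a proteoglycan that binds collagen, at −3.04. The contractile actin genes were negative in 17 of 18 with a median of −1.63, among them Myh11, smooth muscle myosin, lower by at least 63.3-fold in wild type and 34.5-fold in Per2m/m cells, and Cnn1, an actin-binding protein of smooth muscle, at −3.65. Cnn1 had responses of −0.22, 0.21 and −10.92, so this value came from the Per2m/m pair. In Clk/Clk cells the contractile list had a median response of 0.15 with 13 of 18 above 0, and the collagen list a median of −0.10 with 13 of 30 above 0. Of the p53 targets 19 of 24 were negative with a median of −0.50, among them Pmaip1, a promoter of apoptosis, lower by at least 214-fold in Per2m/m cells, and of the HOX genes, which set position along the body axis, 25 of 35 with a median of −0.62, among them Hoxa10, lower by at least 28.6-fold in wild type and 20.9-fold in Per2m/m cells. Macrophage markers were negative in 14 of 15 with a median of −1.20. The macrophage genes were well above background in 14 of 15 on the mock wild type and 15 of 15 on the mock Per2m/m array, against 8 of 15 on both transfected arrays of these genotypes and 9 and 8 of 15 on the Clk/Clk arrays, so they moved with the matrix and contractile lists. Lyz1 and Tyrobp, a lysozyme and a myeloid adaptor, were lower in wild type cells by at least 84.2-fold and 14.7-fold.

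By size, the genes highest after transfection in all 3 genotypes were Itgb7, an integrin subunit of lymphocytes, at 4.63 ± 1.32, then Pianp, Rhox5, Cdsn, Oasl1, Bnc1, Rnf183, Sigirr, Dlk1 at 2.73 ± 0.94 and the chemokine Ccl5 at 2.67 ± 0.86. Itgb7 had responses of 3.65, 2.13 and 8.10 in wild type, Clk/Clk and Per2m/m cells, and the place of Rhox5 came from the Per2m/m pair, as its responses below show. The lowest were Plac8 at −6.13 ± 2.09, then Srpx, Lce1f, Loxl2, Atp9a, Hoxa10, Vip, B3gnt5, Wt1 and Avpr1a. Plac8 had responses of −9.20, −0.39 and −8.81. Wt1, a transcription factor of mesothelium and kidney, was lower by at least 15.2-fold in wild type and 10.4-fold in Per2m/m cells, and by 2.25 in log2 in Clk/Clk cells. None of these genes passed the adjusted threshold.

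In limma, 0 of 17282 genes passed for transfection (lowest adjusted p 0.696) and 799 had an unadjusted p under 0.05, 360 higher and 439 lower, where chance alone gives 864.1. The 9 list calls by camera had adjusted p of 3.79e-15 for DNA replication, 1.76e-08 for mitosis, 1.47e-05 for DNA repair and for collagen, 2.55e-05 for macrophage markers, 7.05e-05 for contractile genes, 0.00355 for cholesterol synthesis, 0.0142 for p53 targets and 0.0225 for HOX genes. With an estimated correlation each had an adjusted p of 0.864, and with fry the adjusted p lay between 0.506 and 0.842. The other 23 lists had adjusted p by camera of 0.0615 (folate and thymidylate, higher) to 0.863, and adjusted over the list alone, 0 members of each of the 32 lists passed. For interferon-stimulated genes the median was 0.09 while camera gave the direction as lower. Without the transfected Per2m/m array, a fit chosen after seeing the data, DNA replication (2.37e-19), mitosis (5.06e-12), DNA repair (5.84e-05), collagen (0.00191) and macrophage markers (0.00258) were still called, and contractile genes, cholesterol synthesis, p53 targets and HOX genes were not. That fit also called glutathione transferases and UGTs (9.65e-04, lower), folate and thymidylate (0.00891, higher), RAS-MAPK output (0.0201, higher) and epithelial markers (0.0489, lower).

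Within each genotype, the response was widest in Per2m/m and narrowest in Clk/Clk cells. In Per2m/m cells 6792 genes differed at least 2-fold (3234 higher, 3558 lower), in wild type 3348 (1289 higher, 2059 lower) and in Clk/Clk 1369 (647 higher, 722 lower). Ranges in brackets after the median response of a list are over the scalings and background corrections tried, given where the sign turned or the value moved by over 1.5 times. The SD of the response over all genes was 2.07, 1.11 and 0.69 in the same order. With each array scaled to its median, the all-gene median response became 0.31 in wild type and 0.40 in Per2m/m cells, against −0.00 and 0.12 in the values used here, and the split became 2478 higher and 1478 lower in wild type and 4476 and 3086 in Per2m/m cells. With normexp the Per2m/m split became 2377 higher and 2318 lower. In all 3 genotypes 113 genes moved at least 2-fold in the same direction, 17 higher and 96 lower, among them Mcm2 and Rad54l (higher) and Loxl2, a matrix-modifying oxidase, and Hoxa10 (lower). The number expected by coincidence was not estimated, so this count alone does not show a common response. Among genes at least 2-fold apart in both, wild type and Per2m/m shared the direction in 1719 of 2087 (82.4%), wild type and Clk/Clk in 217 of 527 (41.2%), and Clk/Clk and Per2m/m in 328 of 765 (42.9%). The correlation of the responses across genes, which are not independent replicates, was 0.38, −0.05 and −0.04.

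Aldh3a1, which encodes an aldehyde dehydrogenase that oxidises aromatic and lipid-derived aldehydes, was brightest on the transfected Per2m/m array. The brighter probe, A_55_P2101216 (chromosome 11, 61031857 to 61031916), had levels of 1.81 and 1.18 in mock and transfected wild type, 0.89 and 1.01 in Clk/Clk, and 1.90 and 6.53 in Per2m/m cells. Its response was −0.63 in wild type, 0.12 in Clk/Clk and 4.63 in Per2m/m cells, the last a 24.7-fold ratio. The Per2m/m response exceeded that of wild type by 5.26, with a spot-level spread of 0.11, and transfected Per2m/m exceeded transfected wild type cells by 5.35 (40.9-fold). A second Aldh3a1 probe, A_55_P2065562 (chromosome 11, 61031864 to 61031920), was well above background only on both transfected wild type and Per2m/m arrays. It was higher after transfection by at least 8.81-fold in wild type and at least 2805-fold in Per2m/m cells, and the transfected Per2m/m array exceeded the transfected wild type array by 8.58. The probes thus gave opposite directions in wild type. In limma the Per2m/m coefficient of Aldh3a1 was 2.72 ± 1.48 (adjusted p = 0.936), and its response ranked 209 of 17282 genes in Per2m/m cells. Between the mock arrays the brighter probe differed little, at 1.90 in Per2m/m and 1.81 in wild type cells.

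**Figure D2:**
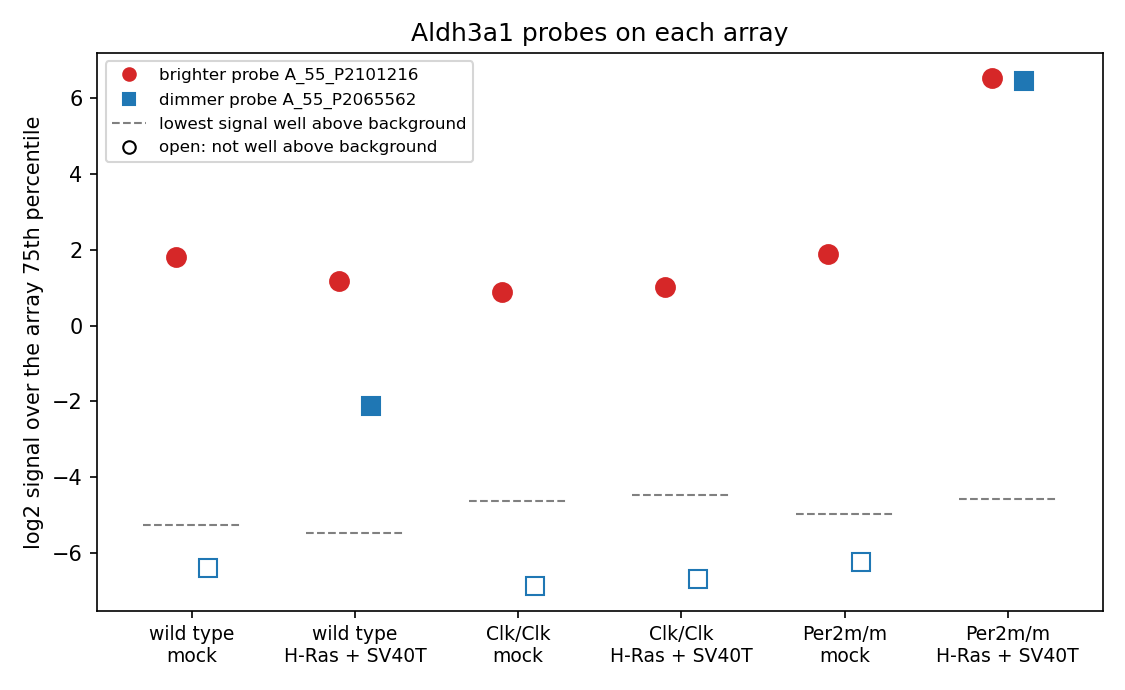
Level of the brighter (circles) and the dimmer Aldh3a1 probe (squares) on each of the 6 arrays, as log2 signal over the array's 75th percentile, with open symbols where a probe was not well above background and dashed lines at the lowest signal well above background on that array. The brighter probe read 6.53 on the transfected Per2m/m array and 0.89 to 1.90 on the others, and the dimmer probe was well above background on 2 arrays.

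Lists of drug and aldehyde handling varied in the transfected Per2m/m cells. Some genes stand in several of these lists, among them Gstm1, Nqo1 and Ugt1a6b, so the lists are not independent. NRF2 targets, which carry the response to oxidants and electrophiles, had a median response of 1.09 (0.68 to 1.37) in Per2m/m cells with 12 of 23 at least 2-fold higher, against 0.04 in wild type (−0.15 to 0.36) and 0.14 in Clk/Clk cells. Gstm1, a glutathione transferase, had a response of 3.85 in Per2m/m cells, Slc7a11, the cystine importer, of 3.43, and Gclc, which limits glutathione synthesis, of 2.35. Aryl hydrocarbon receptor targets, of which Aldh3a1 is 1, had medians of −0.14 (−0.14 to 0.17), −0.54 (−0.58 to −0.23) and 1.55 (0.67 to 1.83). In Per2m/m cells 3 of 8 were at least 2-fold higher and 2 at least 2-fold lower, with the glucuronosyltransferase Ugt1a6b at 5.41 and the cytochrome Cyp1b1 at −7.55. Glutathione transferases and UGTs had medians of −0.59 (−0.59 to −0.27), −0.76 (−0.80 to −0.46) and 1.03 (0.61 to 1.31), and 0.73 in Per2m/m cells with dim members at their bound. Aldehyde dehydrogenases had medians of −0.42 (−0.65 to −0.10), 0.09 (−0.08 with dim members at their bound) and 0.23 (0.18 to 0.50), with 6 of 19 at least 2-fold higher and 7 at least 2-fold lower in Per2m/m cells, where Aldh5a1, which degrades a product of GABA, was at least 99.5-fold lower. Drug efflux transporters had medians of −0.12 (−0.12 to 0.19), −0.09 (−0.10 to −0.03) and 0.44 (0.36 to 0.72). Among 10000 random lists the Per2m/m medians lay at percentile 66.1 for aldehyde dehydrogenases, 77.8 for efflux transporters and 83.5 for folate and thymidylate. The multidrug transporter genes Abcb1a and Abcb1b had responses of 3.07 and 2.45 in Per2m/m cells and Abcg2 of −4.97. Folate and thymidylate genes had medians of 0.56 (0.41 to 0.88), 0.35 and 0.40 (0.35 to 0.68), and BCL2 family genes of −0.03 (−0.24 to 0.28), −0.05 (−0.05 to 0.01) and −0.65 (−0.83 to −0.37).

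Clock lists were called in no coefficient (camera, adjusted p of 0.205 to 0.873). Core clock genes had median responses of 0.01 in wild type (−0.03 to 0.33), 0.03 in Clk/Clk (−0.00 to 0.03) and 0.88 in Per2m/m cells, with 15 of 25 above 0, 11 at least 2-fold higher and 3 lower in the last. CLOCK-BMAL1 E-box targets had medians of −0.02 (−0.05 to 0.29), 0.12 and 1.13 (0.71 to 1.41), with 8 of 16 at least 2-fold higher in Per2m/m cells. Most of these targets also belong to the core clock list, so both medians rest in large part on the same genes. Nr1d2, a nuclear receptor that represses Bmal1, had a Per2m/m response of 3.01, Ciart, a repressor of the clock, of 2.53, and Arntl2, a paralogue of Bmal1, of −4.50. In mock cells both E-box medians were below 0 against wild type, at −0.40 in Per2m/m and −0.51 in Clk/Clk cells. The values stand on the same transfected Per2m/m array that lacked the sex-linked genes.

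By difference in response, the genes furthest above wild type in Per2m/m cells were Slpi, a secreted protease inhibitor, with −3.28 in wild type against 11.14, then Rhox5, Blnk, Aqp5, Dnajc22, Tmem41b, Pgbd5, Xlr, Phactr1 and Xdh at differences of 10.18 to 7.01. Rhox5, an X-linked homeobox gene of the reproductive tract, had responses of 0.32 in wild type and 10.50 in Per2m/m cells. The furthest below were Cnn1 at −10.70, Hspb1, a small heat shock protein, at −9.72, Myl9, a myosin light chain, at −9.59, then Actg2, Cxcl12, Fst, Cyba, Lrrc32, Nsg1 and Ctsh at −8.72 to −8.33. Contractile genes as a list were at least 2-fold lower in 16 of 18 in Per2m/m cells, with a median response of −3.26 (−3.01 with dim members at their bound), against −0.41 (−0.61 to −0.09) in wild type and 0.15 in Clk/Clk cells. Tagln and Acta2, markers of contractile cells, were lower by 8.57 and 6.00 in log2, and the median lay below that of every one of 10000 random lists. Collagen genes had medians of −0.80 (−1.02 to −0.48), −0.10 and −2.20 (−1.85 with dim members at their bound), and senescence regulators of −0.23 (−0.31 to 0.09), −0.05 (−0.05 to −0.02) and −1.80. The cell cycle inhibitors Cdkn2a and Cdkn2b had Per2m/m responses of −3.82 and −6.56. RAS-MAPK output genes had medians of 0.47 (0.30 to 0.79) and 0.37 in wild type and Clk/Clk cells and −1.72 (−1.79 to −0.99) in Per2m/m cells. Among them Areg, an EGF receptor ligand, had 5.97 in wild type, and Hbegf, another, −3.56 in Per2m/m cells. RAS genes had medians of −0.34 (−0.50 to −0.03), 0.42 and −1.22.

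**Figure D3:**
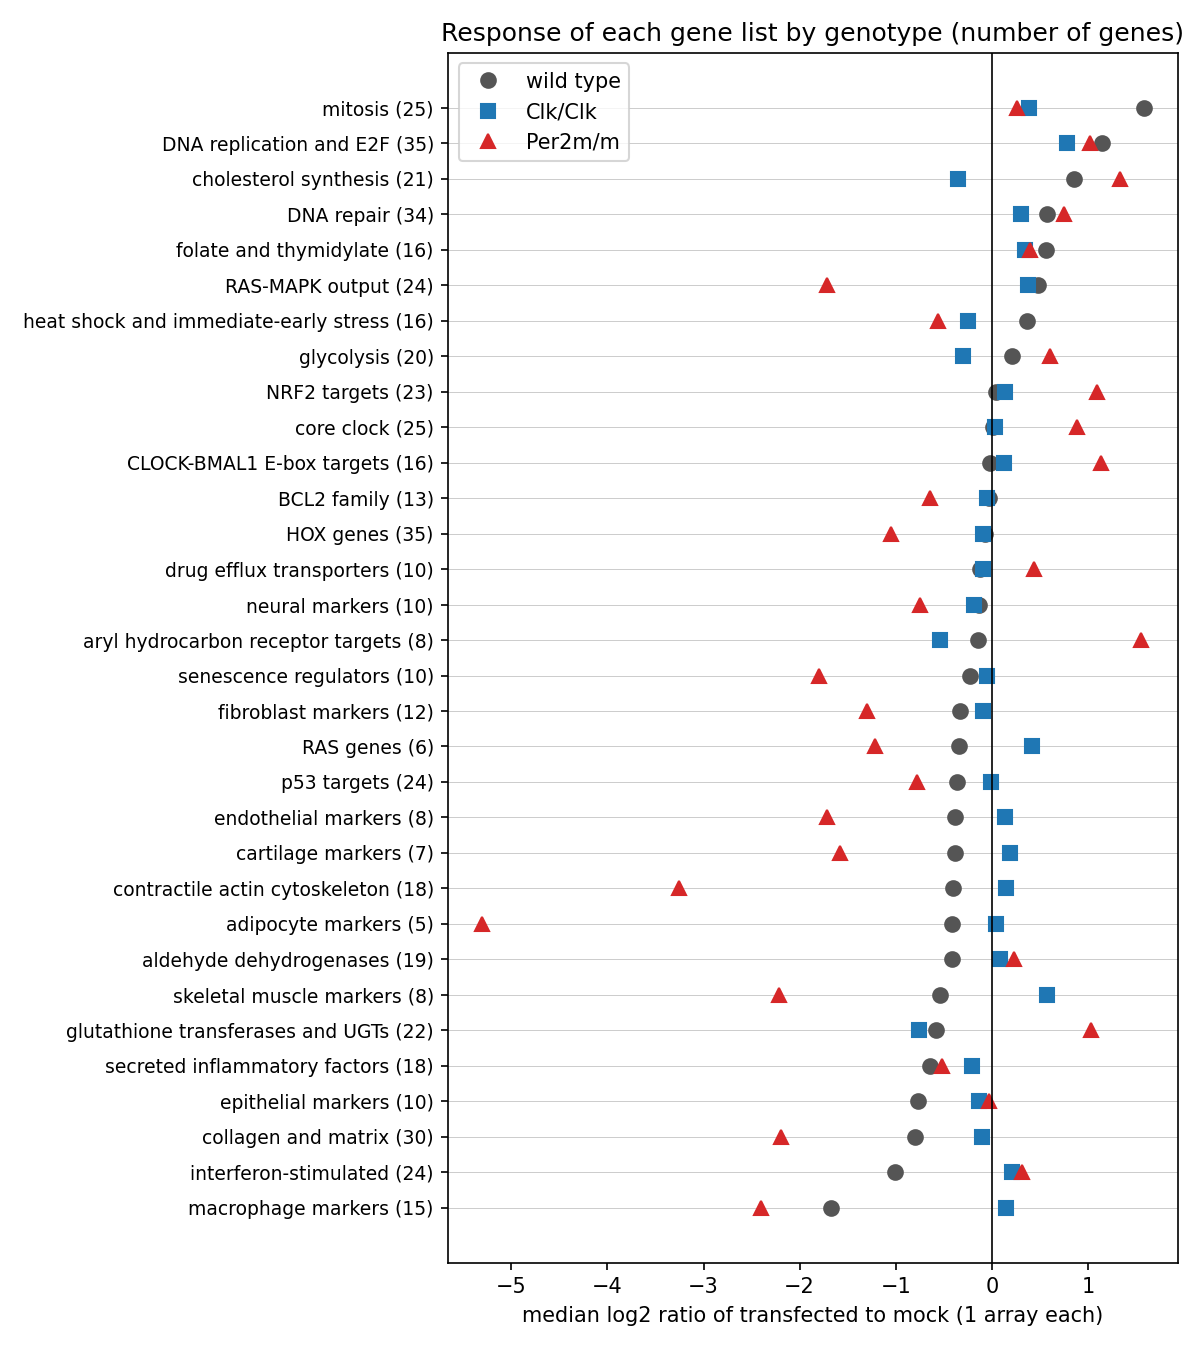
Median log2 ratio of the transfected to the mock array (horizontal axis, 1 array each) for the 32 gene lists with at least 5 measured genes (vertical axis), with circles for wild type, squares for Clk/Clk and triangles for Per2m/m. Per2m/m medians ranged from −5.31 for adipocyte markers to 1.55 for aryl hydrocarbon receptor targets, and Clk/Clk medians from −0.76 for glutathione transferases and UGTs to 0.78 for DNA replication.

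In Clk/Clk cells the response lay furthest above wild type for Plac8, a gene of myeloid and placental cells, by 8.81, then for Sprr1a, Mmp13, Kif1a, Slc16a11, Dpysl4, C1qtnf3, S100b, Slpi and Hoxc13 by 8.25 to 6.49. Sprr1a, a cornified envelope protein, had responses of −4.39 in wild type and 3.86 in Clk/Clk cells, and Mmp13, a collagenase, of −5.13 and 3.01. At the other end stood Klra15, Klra4, Klra16 and Klra1 at −8.89 to −7.22, then Eva1c, Areg, Cbr2, Apln, Gas1 and Ogn at −7.12 to −5.13. The Klra genes encode receptors of natural killer cells and are near-identical copies, so their probes can share targets. Mitosis genes had median responses of 1.59 in wild type, with 24 of 25 at least 2-fold higher, 0.39 in Clk/Clk and 0.26 (0.23 to 0.54) in Per2m/m cells, and cholesterol synthesis genes of 0.85, −0.35 and 1.33. Kif20a, a kinesin of cytokinesis, had a wild type response of 2.16. DNA replication genes had medians of 1.14, 0.78 and 1.02, and DNA repair genes of 0.58 (0.50 to 0.89), 0.30 and 0.75. None of these differences could be tested, because each rests on 4 single arrays.

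Marker lists of other cell types gave a further view of the cultures. Macrophage markers had median responses of −1.68 (−1.68 to −0.93) in wild type, 0.15 in Clk/Clk (−0.02 to 0.15, and −0.13 with dim members at their bound) and −2.40 in Per2m/m cells (−1.96 with the bound). Fibroblast markers had medians of −0.33 (−0.47 to −0.02), −0.09 (−0.09 to −0.01) and −1.30 (−1.42 to −0.85, and −0.89 with the bound), with the surface protein Thy1 at −7.76 in Per2m/m cells. Adipocyte markers had −0.41 (−0.41 to −0.10), 0.04 (−0.00 to 0.05, and −0.61 with the bound) and −5.31 (−5.31 to −3.02). Skeletal muscle markers had −0.54 (−0.54 to −0.22), 0.57 (0.29 to 0.57) and −2.21 (−2.21 to −0.60, and −1.46 with the bound), and cartilage markers −0.39 (−0.39 to −0.07), 0.19 (0.12 to 0.19) and −1.58 (−1.58 to −0.45). Endothelial markers had −0.39 (−0.39 to −0.07), 0.13 (0.03 to 0.13, and −0.08 with the bound) and −1.72 (−1.79 to −0.19, and −0.999 with the bound), and neural markers −0.13 (−0.23 to 0.18), −0.18 (−0.20 to −0.05) and −0.75 (−0.75 to −0.12, and −2.34 with the bound). Epithelial markers had −0.77 (−0.77 to −0.35, and −0.43 with the bound), −0.13 (−0.14 to −0.05) and −0.03 (−0.03 to 0.25), with the basal keratin Krt14 higher by 6.70 and Krt19 lower by at least 87.9-fold in Per2m/m cells. HOX genes had medians of −0.07 (−0.18 to 0.24), −0.09 (−0.09 to −0.06) and −1.05, and glycolysis genes 0.21 (0.01 to 0.52), −0.30 (−0.30 to −0.17) and 0.60 (0.10 to 0.88). Heat shock and immediate-early genes had 0.36 (0.28 to 0.68), −0.25 and −0.56 (−0.77 to −0.28). The p53 targets had −0.36 (−0.51 to −0.04), −0.01 (−0.01 to −0.00) and −0.78 (−0.91 to −0.50), and secreted inflammatory factors −0.64 (−0.90 to −0.33), −0.21 (−0.21 to −0.13) and −0.52 (−0.55 to −0.09). Interferon-stimulated genes had −1.01 (up to −0.64), 0.21 and 0.31 (0.31 to 0.59, and 1.02 with the bound), with Isg15, a ubiquitin-like protein, at −1.72 in wild type and 3.71 in Per2m/m cells.

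Per2m/m cells were compared with wild type over both transfection states. Collagen and matrix genes were lower, with 28 of 30 negative and a median of −0.97. Thbs1 stood at −4.33, Postn, a matrix protein of remodelling tissue, at −4.04, and Timp3, an inhibitor of metalloproteinases, at −3.94. Contractile genes were negative in 16 of 18 with a median of −1.23, led by Cnn1 at −5.06, and NRF2 targets positive in 18 of 23 with a median of 0.52, led by Gstm1 at 1.67 and the epoxide hydrolase Ephx1 at 1.29. The contractile and NRF2 differences lay in the transfected arrays, with medians of 0.06 and 0.06 between the mock arrays and −2.33 and 1.00 between the transfected arrays. Collagen had −0.57 between the mock and −1.27 between the transfected arrays. Macrophage markers were higher on the mock Per2m/m than on the mock wild type array by a median of 1.30.

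The largest positive Per2m/m coefficients were those of Rhox5 at 7.48 ± 3.04, the nuclear receptor gene Nr1h5 (at least 34.6-fold), Rpl39l, Mx1, Trem3, Tpbpa, Slc6a15, Oprd1 and the water channels Aqp5 and Aqp1. Mx1, an interferon-induced GTPase that blocks viruses, was not well above background on either wild type array and higher in Per2m/m by at least 16.2-fold. Trem3, a receptor of myeloid cells, and Tpbpa, a placental gene, were higher by at least 14.0-fold and 8.65-fold, and were well above background on the 2 Per2m/m arrays only. Among the most negative were Syt13, a synaptotagmin not well above background on the transfected Per2m/m array, then Klra15, Serpinb2, Foxf1, Trim12a, Tspan18, Klra4, Cdkn2b and Lrrc17. Trim12a was not well above background on either Per2m/m array and lower by at least 10.8-fold.

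In limma 0 genes passed for Per2m/m against wild type (lowest adjusted p 0.936), and 387 had an unadjusted p under 0.05, 183 higher and 204 lower. Without the mock Per2m/m array 548 genes passed, 173 higher and 375 lower, and this count then rests on the transfected Per2m/m array alone. By camera, collagen (1.2e-06), contractile genes (0.00301) and NRF2 targets (0.0263) were called, each with an adjusted p of 0.864 with an estimated correlation and of 0.755 to 0.842 with fry. Without the transfected Per2m/m array all 3 calls were lost, and macrophage markers (1.05e-05, higher), interferon-stimulated genes (3.38e-04, lower), skeletal muscle markers (0.00196, higher) and aryl hydrocarbon receptor targets (0.0155, lower) were called. Adjusted over the list alone, 1 gene passed, Mx1 among the interferon-stimulated genes, and over all genes 0. The other 29 lists had adjusted p of 0.0683 (epithelial markers, higher) to 0.973, and the sign of the median and of camera differed for DNA repair (0.06, lower), the BCL2 family (−0.04, higher) and neural markers (−0.03, higher). At least 2-fold differences numbered 1531 between the mock arrays (753 higher, 778 lower) and 5334 between the transfected arrays (2540 higher, 2794 lower), and with normexp these splits were 291 higher and 200 lower, and 1839 higher and 1737 lower. With quantile normalization the mock split was 778 higher and 684 lower.

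Clk/Clk cells differed from wild type in their interferon-stimulated genes, all 24 of which were higher, with a median of 5.55. Oas2, which makes an activator of antiviral RNA decay, was higher by at least 281-fold and not well above background on either wild type array, Isg15 was higher by 5.96 (62.4-fold), Oasl2 by 8.77 ± 1.48, and Stat2, a mediator of interferon signals, by 4.25. At least 2-fold higher were 24 of 24 between the mock arrays, with a median of 4.61, and 23 of 24 between the transfected arrays, with a median of 6.29. The median response of these genes within Clk/Clk cells was 0.21. Secreted inflammatory factors were higher in 15 of 18 with a median of 2.67, among them the growth factor Csf2 by at least 32.8-fold, the neutrophil attractant Cxcl5 by 5.31 and Il6 by 4.31. Macrophage markers had a median of −1.25 between the mock arrays, and of 0.99 with 13 of 15 above 0 between the transfected arrays (0.14 with dim members at their bound).

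NRF2 targets were lower in Clk/Clk cells, with 20 of 23 negative and a median of −0.68. Nqo1, a quinone reductase, stood at −3.60 and Gsta2, a glutathione transferase, was lower by at least 8.06-fold. DNA replication genes were negative in 29 of 35 with a median of −0.48, and mitosis genes in 24 of 25 with a median of −0.45. Mitosis genes were higher by 0.20 between the mock arrays and lower by a median of −1.19 between the transfected arrays. By size, the highest genes were Saa3, an acute phase protein (at least 3751-fold), Dchs1, a cadherin (at least 248-fold), the chemoattractant Rarres2 at 9.11 ± 0.99, Trim30a, Oasl2, Gdf10, Tac1, Oas2, Arhgap9 and Vat1l. Among the lowest were Col2a1, the collagen of cartilage (at least 92.5-fold), Cthrc1, Tnmd, Ebf2, Perp, Mdga1, Lgr6, Sobp and Foxd1.

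In limma 0 genes passed for Clk/Clk against wild type, with a lowest adjusted p of 0.176, and 1604 had an unadjusted p under 0.05, 1043 higher and 561 lower. Camera called interferon-stimulated genes (2.54e-25), secreted inflammatory factors (1.11e-05), NRF2 targets (0.00281), DNA replication (0.0152) and mitosis (0.0488). With an estimated correlation the adjusted p was 0.892 for mitosis and 0.864 for the other 4, and with fry 0.506 to 0.842. Without the transfected Per2m/m array the mitosis call was lost (0.0862). Adjusted over the list alone, 23 of 24 interferon-stimulated genes, 3 secreted factors, 2 aryl hydrocarbon receptor targets (Nqo1 and Ahrr), 1 NRF2 target (Nqo1) and 1 epithelial marker (Cldn3) passed, and over all genes 0. The other 27 lists had adjusted p of 0.122 (folate and thymidylate, lower) to 0.933, and median and camera differed in sign for aldehyde dehydrogenases (−0.06, higher) and neural markers (−0.00, higher). Between the mock arrays 3632 genes differed at least 2-fold (1807 higher, 1825 lower) and between the transfected arrays 4281 (2382 higher, 1899 lower). Scaled to array medians these splits were 1300 higher and 3154 lower, and 1456 higher and 6366 lower. With normexp the mock split was 1023 higher and 997 lower, and with quantile normalization the transfected split was 2032 higher and 2075 lower.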

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

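Of the tests in this part, those of degraded RNA, of chromosomes and of genes shared between pairs of arrays were written before their results, and all others were chosen after the result was seen. Results were picked out here because the response ran in opposite directions in 2 genotypes by at least 0.5 (log2) on each side, which left out lists such as RAS-MAPK output and cholesterol synthesis with a smaller value on 1 side, and none of these differences was tested, since each rests on single arrays. The response of Aldh3a1 was higher in Per2m/m than in wild type cells by 5.26 on the brighter probe. Its opposite directions depend on that probe. The second probe was higher after transfection in both, by at least 8.81-fold in wild type and at least 2805-fold in Per2m/m cells. The median response of aryl hydrocarbon receptor targets was higher in Per2m/m than in Clk/Clk cells by 2.08 (0.901 with normexp). This list was split in Per2m/m cells, with 3 of 8 members at least 2-fold higher and 2 at least 2-fold lower. Its median level was 0.77 on the mock and −0.95 on the transfected Per2m/m array. Between transfected Per2m/m and transfected wild type cells the median over its genes was 0.26. The median response of glutathione transferases and UGTs was higher in Per2m/m cells than in wild type by 1.62 and than in Clk/Clk by 1.79 (1.04 and 1.07 with normexp). That of skeletal muscle markers was higher in Clk/Clk than in wild type cells by 1.11 (0.702 with normexp), and the Per2m/m value minus the Clk/Clk value was −2.79 (−0.886 with normexp).

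The transfected Per2m/m array stood apart from the other 5 arrays. Degraded RNA is unlikely to account for it among probes well above background on all 6 arrays, the only ones used. There, probes upstream and downstream in 1820 transcripts differed by a median of 0.0265 (0.00332 to 0.0518), inside the range of the other arrays (−0.0769 to 0.0266). Probes lost to background on this array were left out, so a loss that complete was not tested. A wrong label among the 3 genotypes would not by itself account for the array standing apart. Its correlations were 0.857 and 0.892 with mock and transfected wild type, 0.855 with both Clk/Clk arrays and 0.854 with mock Per2m/m. It had 0 of 4 sex-linked genes well above background, against 4 of 4 on both wild type and 3 of 4 on both Clk/Clk arrays. Whether the label is right stays open. Of 26 genes that set mock Per2m/m apart, 2 (7.69%) were shared, against 63 of 76 (82.9%) in Clk/Clk and 1 of 6 (16.7%) in wild type. Wild type met the condition written for a wrong label as well, with no label in doubt, so meeting it does not point to a wrong label. A later count gave 17 genes shared with mock Per2m/m, 15 with mock Clk/Clk, 2 with mock wild type and, the most, 176 with transfected wild type (167 of them lower on both). A clone with gained or lost chromosomes could account for the array standing apart, and its test cannot tell. Of 20 chromosomes tested, 6 lay outside the random range, against 4 in wild type and 8 in Clk/Clk. This is a poor criterion, because the range narrows with the spread of each pair (0.687 in Clk/Clk, 2.07 in Per2m/m). The SD of chromosome medians (0.181 in Per2m/m, 0.108 in wild type, 0.076 in Clk/Clk) grows with that spread, so its order does not favour a chromosome change. Furthest outside in Per2m/m cells were chromosome 17, at 0.54 (limit 0.22), and chromosome 14, at −0.32 (limit −0.05). Chromosome Y was not among those tested. Its genes Ddx3y and Eif2s3y were not well above background on the transfected Per2m/m array, so a loss of Y stays open. The low share of spots well above background on this array (49.3%) was not tested as a cause.

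The interferon-stimulated genes were higher on both Clk/Clk arrays. Macrophages in the Clk/Clk cultures are unlikely to account for it on the mock arrays, where the median level of macrophage markers was lower than on mock wild type (−2.62, and −1.25 as the median over genes). Between the transfected arrays that median over genes was 0.99 (0.14 with dim members at their bound), so macrophages are not excluded there. A response to the H-Ras and SV40T vector beyond that to the mock is unlikely as well, since the median ratio of transfected to mock Clk/Clk cells was 0.21. A response common to mock and transfected cells would cancel in this ratio and is not excluded. A single preparation of cells shared by both arrays may account for it, and the correlation of 0.981 between them cannot tell this from an effect of the genotype.

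The 2 Aldh3a1 probes differed in direction in wild type cells. Signal of another transcript on the brighter probe could hide a rise there, and adding the rise of the dimmer probe to such a signal predicted 0.0878 where −0.63 was measured. A rise that small would not be seen on the brighter probe, so such a signal can hide it. The brighter and the dimmer probe had signals of 38836 and 37158 on the transfected Per2m/m array. On mock wild type they had 1718 and 5.78 (not well above background), and on transfected wild type 1433 and 146. Most of the brighter probe's wild type signal was thus not shared by the dimmer probe, and the fall lay in that part. What that part is, and why it fell, was not tested. Both probes were brightest on the transfected Per2m/m array, so the open question of its label bears on Aldh3a1 as well.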

How the results depend on the processing

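The Aldh3a1 difference and ratio below kept their direction. The wild type response of Aldh3a1 turned with the probe, and splits into higher and lower genes and the sign of some list medians turned with the scaling. The count of 0 genes at an adjusted p under 0.05 for each coefficient held under every other setting fixed beforehand, except 9 genes for Clk/Clk without the transfection term, and leaving out arrays gave 0 to 0 for transfection and Clk/Clk and 0 to 548 for Per2m/m, the highest without the mock Per2m/m array, which leaves 1 Per2m/m array assumed to vary like the others. At an unadjusted p, chosen after seeing the data, the counts were 799, 387 and 1604. The 2-fold counts of 3348, 1369 and 6792 (wild type, Clk/Clk, Per2m/m) became 1887 and 470 in wild type and Clk/Clk with normexp, 1647, 496 and 4149 with genes well above background on all 6 arrays, and 1109, 315 and 3455 at 4-fold, the last by construction. With both arrays well above background, also chosen later, they were 818 in Clk/Clk and 4368 in Per2m/m. The Aldh3a1 difference of 5.26 and ratio of 5.35 became 5.08 and 5.18 with normexp, 5.02 and 5.09 with quantile normalization, 5.04 and 5.11 with the authors' table, 6.84 and 6.97 with the mean of probes, and 8.43 and 8.58 with the second probe, chosen later. Of 17 list calls, 0 held with camera at an estimated correlation and 0 with fry. With 2 residual degrees of freedom these settings could call little. The interferon-stimulated genes of Clk/Clk cells, 24 of 24 higher with a median of 5.55, had an adjusted p of 0.864 by camera with an estimated correlation and 0.506 by fry. The loss of the calls therefore does not tell lists that moved from lists that did not. For 100 values of named genes, each compared under each setting, 548 comparisons stayed the same and 192 moved. The cause was not tested. Signal over background limits the dim side of each ratio to a bound.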

Other observations

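Tests in this part were chosen after the results were seen, and the genes of this paragraph and the next were too. Serpinb5, a serpin of epithelial cells, Trim29, a protein of basal epithelium, and Luzp4, a gene of testis and tumours, were well above background on the transfected Per2m/m array and on no other, with responses of at least 6.07, 6.63 and 5.67 in log2.

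The Zscan4 genes, which mark a passing state of embryonic stem cells, were well above background on both transfected wild type and Per2m/m arrays and on no others. In wild type the response was at least 0.91 for Zscan4a and 1.26 for Zscan4f, and in Per2m/m cells at least 4.35 and 4.75. These genes are close copies, so their probes can share targets.

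A hypothesis of this re-analysis was that imprinted genes as a class are lower after transfection in all 3 genotypes. It came from H19, Mest, Peg3 and Zim1, and the list of 31 others was written after several of their values had been seen. Of these, 28 were measured, with median responses of −1.31 in wild type, 0.05 in Clk/Clk and −1.36 in Per2m/m cells. The highest percentile among random lists was 63.8, in Clk/Clk cells, so the hypothesis did not hold there. At least 2-fold lower were 15 of 28 in wild type, 15 in Per2m/m and 0 in Clk/Clk cells. Meg3, a maternally expressed RNA, had responses of −2.66, −0.15 and −8.26, and Dlk1, its paternally expressed neighbour, of 4.49, 0.31 and 3.39.

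The arrays were also split in every other way into 3 and 3 and fitted again. The real split by transfection gave 0 genes at an adjusted p under 0.05 and the highest other split 1255. That 10 of 10 splits gave at least as many follows from the real count of 0 and tests nothing. At an unadjusted p under 0.05 the real split gave 799 and the highest other 4690, and 4 of 10 gave at least as many, but the splits that part 1 pair come as identical fits in twos and contrast that pair alone. The 4 splits that part all 3 pairs, as the real split does, gave 799 (real), 835, 249 and 243. The 10 splits are too few for a share under 0.05. The splits with 1255 genes part only the Per2m/m pair, so they restate its wide response. Its SD over genes was 2.07, against 1.11 in wild type and 0.69 in Clk/Clk cells.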
